A study of Saccharomyces cerevisiae with 36 samples.

How the data were processed

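RNA was sequenced from 6 natural isolates of the budding yeast Saccharomyces cerevisiae grown in 3 media, with 2 libraries for each strain and medium, 36 libraries in all. The media were YPD, a rich laboratory medium, SynH, a synthetic lignocellulosic hydrolysate that carries toxins, and SynH -HTs, the same hydrolysate without the toxins. Per the labels, cells grew for at least 3 generations to log phase at an optical density (OD600) near 0.5, total RNA was isolated by a hot phenol method, ribosomal RNA was removed, and libraries were made with a stranded total RNA kit. The labels call Y7568, YPS128 and UWO.S05.22-7 resistant to SynH, NCYC361 and K11 sensitive, and NCYC3290 of medium resistance. The replicates are described as biological and as collected on different days, and no further record of days or batches was used here. The NCYC361 libraries in SynH are titled SynHv, and they were taken as SynH because their medium label says so.

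The submitters' processing notes name Trimmomatic 0.30, Bowtie2 and HTSeq 0.6.0. The genome build and annotation used for alignment, and whether counting used the strand, are not given in the sources used here, so genes that overlap others and genes with near-identical copies are marked as uncertain where they are named. The deposited table holds 6717 rows of features and 6 rows that name no gene, and its values are log2 RPKM (reads scaled by gene length and by the library total) made by the authors. From the values, the authors added 1 read to each count before taking the log2. The size of a single read is visible in each library, so reads were recovered from the values and the coding lengths of the RefSeq annotation R64. Of the 6025 rows matched to a RefSeq locus tag, 6013 gave whole reads in all 36 libraries within 0.05 reads, and 99.83% of all values in matched rows were whole. The remaining 692 rows had no match in that annotation and took no part in checks that need coordinates or sequence. Coordinates are those of R64, which may not be the build the authors used, and lengths are coding lengths.

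The recovered reads in genes ranged from 2204823 to 32836466 per library. The deepest library was YPS128 in SynH replicate 2, and the next held 8045825 reads. Reads in genes made up 66.9 to 75.1% of the total by which the authors divided. A coding length of 1 kb with 0 reads lies at a log2 RPKM between -1.69 and -5.49, depending on the library. A log2 change on this scale includes the added read, which can understate the change of genes with few reads. Because library totals differ, the added read can also give a change where none was measured. ADH7 in K11, with 0 reads in SynH and in SynH -HTs, has a toxin response of -0.26 on this scale. The reads carry no molecular identifiers, so counting precision covers sampling only.

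Tests were made with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with an intensity-dependent prior variance, no further scaling and 1 mean for each of the 18 groups of strain and medium. The 5927 features with a mean of at least 1 RPKM were tested. P-values were adjusted by Benjamini and Hochberg for each comparison, with a threshold of 0.05. The toxin response is SynH minus SynH -HTs, the base medium response is SynH -HTs minus YPD, and the complete hydrolysate response is SynH minus YPD. Each was averaged over the 6 strains with equal weight. The toxin response was also tested within each strain. Differences among the 6 strains were tested with limma's F test for the toxin response, for the base medium response and for the mean level over the 3 media. Resistant and sensitive strains were compared with the strain as the replicate, 3 against 2, on the means of the 2 libraries, without NCYC3290. Errors of a log2 change are standard errors from the fit. They reflect the libraries within strains and not the spread between strains, for which ranges are given for a part of the genes.

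The comparisons, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Several tests were possible depending on the unit, and the one fixed for values already on the log2 scale was used. For the toxin and base medium responses the 12 largest rises and 12 largest falls are named among genes past the threshold, with the same sign in all 6 strains and a mean of at least 10 RPKM. Up to 4 members with the smallest adjusted p are named from each gene list described in detail, and PDR5, SNQ2, RPN4, YAP1, LEU3 and MCH4 are named whatever their values. A list member that this rule names is not reported here. For the complete hydrolysate 5 and 5 genes are named, for single strains 3 and 3, and for strain differences the 10 smallest adjusted p. Between the classes, up to 5 genes per direction are named, or the 5 smallest p where none passed. Which lists were described in detail was chosen after the values and their dependence on the processing had been seen. The counts of all lists are given, and the 150 list members left unnamed by that choice were checked in the same way.

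The 33 gene lists cover drug efflux, oxidative stress, aldehyde conversion, weak acid response, protein quality control, ribosomes, amino acid, vitamin, metal, phosphate and sugar pathways, sterols, cell wall, osmotic stress, DNA damage, and markers of haploid and sporulating cells. Each was tested with camera of limma, which compares a list with all other genes, with a preset correlation of 0.01 between genes. The test was repeated with an estimated correlation. Counts of list members past the threshold are over all tested genes, and the count adjusted over the list alone stands beside them. AAD16 was the only listed gene that matched no row of the table.

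Replicates were checked before averaging. The chi-square per degree of freedom between the 2 libraries of a group was 4.64 to 112.72, and their correlation across genes was 0.946 to 0.992, so no library was a copy of its partner.

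The test was run on simulated data with 200 genes changed by known folds and a spread between replicates of 0.25 on the log2 scale. For the averaged toxin response it recovered 95% of 1.5-fold changes and 99% of 2-fold changes. Within single strains it recovered 7% and 47%. Of strain differences in the toxin response it recovered 16% at 2-fold and 96% at 4-fold. Of class differences in the toxin response it recovered 72% at 2-fold and 100% at 4-fold, in simulations without variation between strains of a class. The simulated spread was drawn independently for each library, and changes in the averaged responses were equal in all strains. In the data the replicate differences in SynH -HTs were shared by the strains (correlations of 0.62 to 0.86). The replicate difference averaged over strains had an SD across genes of 0.56 in SynH -HTs, 0.26 in SynH and 0.15 in YPD. The spread was thus also unequal between media. The recoveries given, for the averaged toxin response and for the other comparisons, therefore do not carry over to the data.

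Alternatives covered normalization, the filter, the variance trend, the number of added reads, replicate blocks, libraries and strains left out, the unit of replication, and the place of NCYC3290. Median scaling, a correction for base composition, limma's voom on the recovered reads, further blocks and the exclusion of either replicate of SynH -HTs were added after the data were seen. Near-identical copies were found with BLAST+ 2.17.0 as genes aligned over at least 50% of their coding length at 95% identity or more. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.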

Results

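Transcript levels were measured by RNA sequencing in 6 natural isolates of Saccharomyces cerevisiae that differ in their tolerance of lignocellulosic hydrolysate, the sugar-rich liquor made from plant biomass. The isolates were NCYC361 and K11, labelled sensitive, NCYC3290, labelled of medium resistance, and Y7568, YPS128 and UWO.S05.22-7, labelled resistant. Each was grown in YPD, in synthetic hydrolysate with toxins (SynH) and in synthetic hydrolysate without them (SynH -HTs), with 2 biological replicates per strain and medium. Each medium thus had 12 libraries and each strain 6. Libraries held 2204823 to 32836466 reads in genes. The design addresses how yeast responds to the toxins, how it responds to the base medium, and how these responses differ among strains and between resistant and sensitive strains.

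The toxins raised transcripts of efflux pumps and of enzymes that reduce aldehydes. PDR12 (YPL058C, chromosome XVI 445842 to 450377), an exporter of organic acid anions, was 23.6-fold higher in SynH than in SynH -HTs averaged over the 6 strains (log2 change 4.56 ± 0.09 SE, adjusted p = 1.25e-21, range over strains 2.07 to 6.29). The drug efflux pumps SNQ2 (YDR011W) and PDR5 (YOR153W) were 6.51-fold and 4.04-fold higher, each in all 6 strains. The alcohol dehydrogenase gene ADH7 (YCR105W, chromosome III 309070 to 310155) had a mean log2 change of 8.64 ± 0.13, and rose in 5 strains. In K11 it had 0 reads in SynH and in SynH -HTs, so no fold is given for that strain, and the 6-strain mean includes it at the level of the added read. ARI1 (YGL157W), an aldehyde reductase, was 13.6-fold higher (3.77 ± 0.14, range 0.33 to 6.25).

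Beyond PDR12 and ARI1, the 12 largest rises that met the rule for naming included TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene (4.98 ± 0.18, 31.5-fold), and HXK1, a hexokinase gene (4.09 ± 0.24). SNG1 (3.72 ± 0.20), the sulfate permease gene SUL2 (3.2 ± 0.12) and the inositol synthesis gene INO1 (3.10 ± 0.14) were also among them. The small heat shock protein genes HSP26 (3.13 ± 0.25) and HSP42 (2.76 ± 0.29), the arginine synthesis gene ARG1 (2.93 ± 0.11), SPO24 (3.00 ± 0.17) and TMA10 (3.36 ± 0.27) completed the set. TMA10 had at most 3 reads per strain in SynH -HTs, so its fold depends on the added read. The largest falls under this rule were smaller, and THI73, which fell further on average (-2.58 ± 0.26), rose in 1 strain and so was left out. The thiamine transporter gene THI7 was lower by 4.05-fold (-2.02 ± 0.09) and the uridine permease gene FUI1 by 3.85-fold (-1.95 ± 0.13). TCB2, YNL095C and PNS1 followed at -1.32, -1.32 and -1.31, and SAM3, HMS2, AAH1, RFU1, INA1, CSS1 and RSN1 lay between -1.22 and -1.06. Among the rises the changes ranged over strains from 0.58 to 6.29 for HXK1, 1.59 to 6.34 for HSP26, 1.31 to 5.08 for SUL2, 0.83 to 4.42 for HSP42 and 0.97 to 4.5 for INO1, far wider than the standard errors, which reflect the libraries within strains. The rule for naming required the same direction in the 6 strains and a passed test, so neither is a finding about these 24 genes. Their adjusted p ran from 1.25e-21 to 8.42e-06. Of the genes named by function, the proteasome regulator gene RPN4 was 1.97-fold higher (0.98 ± 0.12, adjusted p = 8.63e-07) and MCH4 was 2.27-fold higher (1.18 ± 0.14). With strains as the unit HXK1 and PNS1 lost their calls (adjusted p = 0.0584 and 0.0543). With means over strains for each medium and replicate number, which keep libraries of a shared number together, YNL095C, PNS1, HMS2, CSS1, RSN1, RPN4 and MCH4 lost theirs (adjusted p = 0.0612 to 0.116). YAP1 (0.39 ± 0.16, adjusted p = 0.0618) and LEU3 (-0.11 ± 0.19, adjusted p = 0.734) did not pass.

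**Figure D1:**
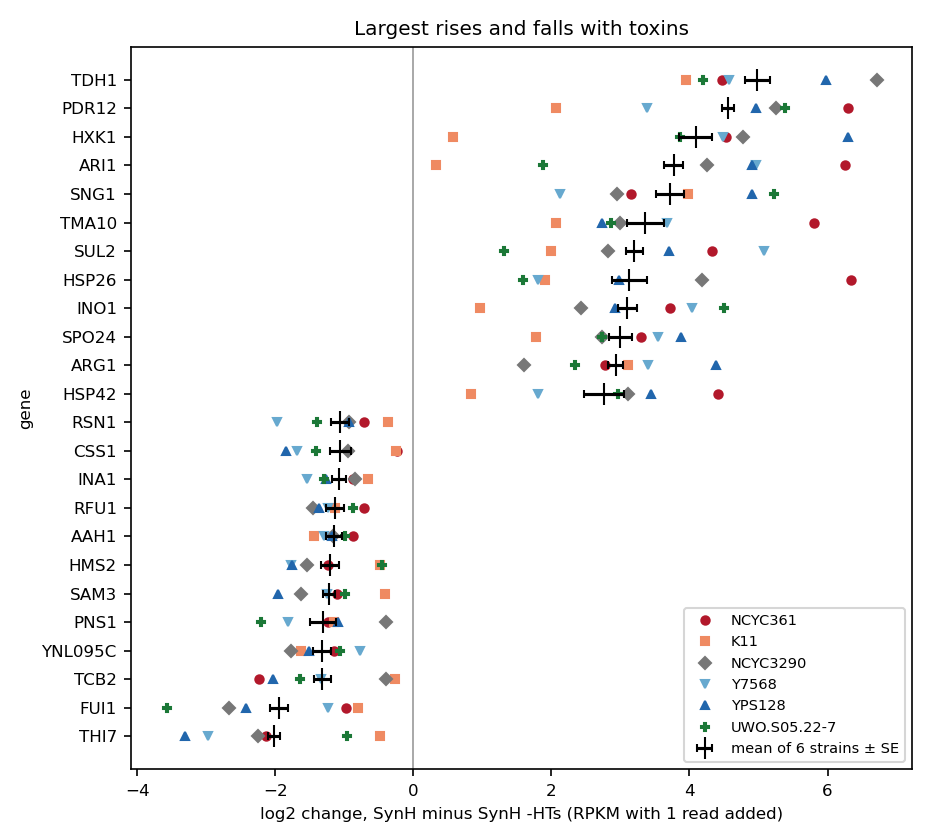
Log2 change from SynH -HTs to SynH in each of the 6 strains (coloured points), with the mean over strains and the standard error from the fit in black. That error reflects the libraries within strains and not the spread between strains. The genes are the 12 largest rises and 12 largest falls that met the rule for naming. The means run from 4.98 for TDH1 to -2.02 for THI7, and the rises spread more widely between strains than the falls.

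Several stress and detoxification lists rose together in the toxin response. Of 24 tested genes induced by general stress, 22 rose and 0 fell (23 rose adjusted over the list alone), with a median 1.09 above that of all genes on the log2 scale. HXK1, the glucokinase gene GLK1 (2.42 ± 0.18), the glycogen phosphorylase gene GPH1 (3.41 ± 0.27) and HSP26 led that list. Of 20 aldehyde reductase and dehydrogenase genes 18 rose (18 adjusted over the list alone), among them ADH7, ARI1, ADH6 (0.88 ± 0.06) and AAD4 (2.10 ± 0.16). Of 14 drug efflux targets of Pdr1 and Pdr3, 11 rose and 1 fell (11 and 1 adjusted over the list alone), led by SNQ2, PDR5, ICT1 (1.89 ± 0.11) and YOR1 (0.96 ± 0.07). Of 14 weak acid response genes 9 rose (11 adjusted over the list alone), with PDR12, HSP30 (2.30 ± 0.24), SPI1 (1.98 ± 0.22) and PHM8 (2.24 ± 0.28) as examples. Of 15 osmotic stress and glycerol genes 12 rose (12 adjusted over the list alone). All 5 lists passed camera with the preset and with an estimated correlation (adjusted p = 0.00367 to 0.0409 with an estimated correlation). Of 17 oxidative stress targets of Yap1, 12 rose (13 adjusted over the list alone), with OYE3 (3.46 ± 0.23), FLR1 (1.66 ± 0.11), PRX1 (1.39 ± 0.14) and TRX2 (0.64 ± 0.07) as examples. That list passed camera with the preset correlation (adjusted p = 1.9e-05) and not with an estimated one (adjusted p = 0.0805).

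Genes of energy metabolism and amino acid pathways also rose with the toxins. Of 18 genes of the tricarboxylic acid cycle 16 rose (17 adjusted over the list alone), with IDP1 (1.16 ± 0.06), SDH2 (1.18 ± 0.09), CIT1 (1.20 ± 0.09) and IDH1 (0.83 ± 0.07) as examples. Of 11 glucose-repressed genes 7 rose (9 adjusted over the list alone), including the invertase gene SUC2 (1.26 ± 0.08), GAL3 (1.88 ± 0.19), JEN1 (1.85 ± 0.23) and MTH1 (1.55 ± 0.26). Of 7 genes of aromatic amino acid breakdown 6 rose (7 adjusted over the list alone), led by ARO9 (1.37 ± 0.10), ARO10 (2.15 ± 0.15), BAT2 (1.43 ± 0.14) and ESBP6 (0.48 ± 0.10). These 3 lists passed camera with both correlations (adjusted p = 0.0068 to 0.0409 with an estimated correlation). Of 31 genes of the respiratory chain and ATP synthase 26 rose and 1 fell (28 and 1 adjusted over the list alone), with ATP17 (0.74 ± 0.05), NDI1 (1.30 ± 0.12), ATP5 (0.56 ± 0.06) and QCR9 (0.75 ± 0.08) as examples. That list passed camera with the preset correlation and not with an estimated one (adjusted p = 0.0805). Of 40 amino acid synthesis targets of Gcn4, 30 rose (32 adjusted over the list alone), with ARG1, ARG4 (2.35 ± 0.11) and LYS1 (1.59 ± 0.10) as examples (adjusted p = 0.0502 with an estimated correlation). Of 23 genes of sulfate assimilation and methionine synthesis 15 rose and 4 fell (16 and 5 adjusted over the list alone), led by SUL2, MET3 (2.28 ± 0.12), MET10 (1.64 ± 0.08) and MET22 (1.15 ± 0.06) (adjusted p = 0.0685 with an estimated correlation). Of 10 branched-chain amino acid genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), led by LEU2 (1.28 ± 0.08), LEU4 (1.24 ± 0.09), GDH1 (0.83 ± 0.09) and OAC1 (1.02 ± 0.14) (adjusted p = 0.109 with an estimated correlation).

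Genes of ribosome production fell in the toxin response. Of 45 ribosome biogenesis genes 36 fell and 0 rose (40 and 0 adjusted over the list alone), with a median 0.78 below that of all genes, and CBF5 (-0.82 ± 0.07), UTP20 (-0.71 ± 0.08), NIP7 (-0.81 ± 0.09) and UTP10 (-0.68 ± 0.09) as examples. Of 132 cytosolic ribosomal protein genes 67 fell and 0 rose (73 and 1 adjusted over the list alone), by smaller amounts, with RPL12A at -0.51 ± 0.06 and RPS0A at -0.38 ± 0.05. RPL18B (-0.64 ± 0.06) and RPL1A (-0.59 ± 0.08) have near-identical copies, so their values are uncertain. Both lists passed camera with the preset correlation and not with an estimated one (adjusted p = 0.152 and 0.186). Of 14 genes of thiamine and pyridoxine synthesis 7 fell and 3 rose (7 and 3 adjusted over the list alone), with THI7, PHO3 (-1.69 ± 0.17), THI73 (-2.58 ± 0.26) and THI2 (-2.02 ± 0.28) as examples (adjusted p = 0.167 with an estimated correlation), and the rises became 1 after quantile normalization and after median scaling. Over strains PHO3 ranged from -3.78 to 1.24, THI73 from -4.95 to 0.91 and THI2 from -5.14 to 0.33. The median of the thiamine and pyridoxine list relative to all genes was 0.67 in NCYC361 and 0.19 in K11, and -1.74 to -0.35 in the other strains. With the SynH -HTs libraries of replicate 1 alone, 45 ribosome biogenesis and 119 ribosomal protein genes fell and 0 rose. With those of replicate 2 alone, 17 and 45 fell and 2 and 21 rose.

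Of the other lists, those of the cell wall and of NAD synthesis passed camera with both correlations. Cell wall integrity genes rose in 12 of 19 (15 adjusted over the list alone, adjusted p = 0.0229 with an estimated correlation) and NAD synthesis genes in 7 of 10, with 1 fall (7 and 1 adjusted over the list alone, adjusted p = 0.0409 with an estimated correlation). Iron regulon genes rose in 13 of 22 with 3 falls (17 and 3 adjusted over the list alone, adjusted p = 0.223 with an estimated correlation). Hexose transporter genes rose in 5 of 10 with 1 fall (6 and 1 adjusted over the list alone, adjusted p = 0.0526 with an estimated correlation). Genes of peroxisomal fatty acid oxidation rose in 5 of 11 (5 adjusted over the list alone, adjusted p = 0.0526 with an estimated correlation). Glycolysis and fermentation genes rose in 7 of 16 (7 adjusted over the list alone, adjusted p = 0.315 with an estimated correlation). Genes under nitrogen catabolite repression rose in 8 of 17 with 2 falls (9 and 2 adjusted over the list alone, adjusted p = 0.118 with an estimated correlation). Unfolded protein response genes rose in 7 of 14 (8 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation). Zinc regulon genes fell in 3 of 9 with 1 rise (3 and 1 adjusted over the list alone, adjusted p = 0.271 with an estimated correlation). These 9 lists passed with the preset correlation. The 8 remaining lists did not pass camera. Among them 4 of 33 proteasome genes rose (1 adjusted over the list alone), 8 of 20 chaperone genes rose and 2 fell (10 and 3), and 3 of 14 phosphate regulon genes rose and 1 fell (3 and 1), which became 2 and 3 after quantile normalization. Ergosterol genes rose in 6 of 24 and fell in 4 (6 and 4), copper genes rose in 1 of 6 (1), and DNA damage genes rose in 5 of 13 and fell in 1 (5 and 1), which became 2 and 2 after quantile normalization. Haploid-specific genes rose in 2 of 13 (1) and sporulation genes in 2 of 10 (0), which became 1 rise and 1 fall, and 0 rises and 1 fall, after quantile normalization. The bracketed counts are those adjusted over the list alone. After median scaling proteasome genes had 10 rises, chaperone genes 10 rises and 4 falls, glycolysis genes 3 rises and ergosterol genes 5 rises and 2 falls. After quantile normalization proteasome genes had 2 rises and hexose transporter genes 3 rises and 1 fall. The phosphate list had a median of 0.05 and a mean of 0.10 with a downward test, and the sporulation list a median of 0.00 and a mean of 0.09 with a downward test.

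Over all genes, 1757 of 5927 passed in the toxin response, 1131 higher and 626 lower, and 302 and 32 of these exceeded 2-fold. The median of all genes was 0.09, and after quantile normalization the counts were 1027 higher and 1217 lower. Of the 1757 genes, 1498 were then called in the same direction and none in the opposite one. The SynH -HTs libraries of replicate 2 stood apart from those of replicate 1 together in all 6 strains, with correlations of the deviations between strains of 0.62 to 0.86 across genes, which are not independent replicates. The median difference of replicate 2 from replicate 1, relative to all genes, was 0.96 for cell wall genes, 0.81 for drug efflux targets, 0.77 for the zinc regulon, 0.76 for the iron regulon, 0.75 for both glycolysis and weak acid genes, and -0.39 for ribosome biogenesis. With replicate 1 of SynH -HTs alone, 10 drug efflux, 21 general stress, 16 aldehyde and 17 tricarboxylic acid cycle genes rose, and with replicate 2 alone 11, 22, 18 and 16 rose. Proteasome genes had 0 rises and 5 falls with replicate 1 alone, and 32 rises and 0 falls with replicate 2 alone. Chaperone genes had 6 and 15 rises, unfolded protein response genes 4 and 12, and glycolysis genes 13 and 6, in the same order. Strains as the unit gave 617 genes, 291 higher and 326 lower, and the means of the 6 strains for each medium and replicate number gave 190, 176 higher and 14 lower. Of the genes named for the toxin response 16 lost the call with strains as the unit, HXK1, PNS1, PHM8, RPL12A, RPL1A, RPS0A, ARO9, ARO10, ESBP6, PHO3, THI73, THI2, IDH1, ATP5, QCR9 and SUC2 (adjusted p = 0.0543 to 0.294). With means over strains 21 lost it, YNL095C, PNS1, HMS2, CSS1, RSN1, RPN4, MCH4, TRX2, UTP20, NIP7, UTP10, RPL18B, RPL12A, RPL1A, RPS0A, GDH1, OAC1, ESBP6, THI2, ATP5 and MTH1 (adjusted p = 0.0552 to 0.402). Leaving out the 6 SynH -HTs libraries of replicate 2 gave 932 higher and 2064 lower, and leaving out those of replicate 1 gave 3163 higher and 544 lower, so the balance of rises and falls over all genes rests on which replicate is used.

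**Figure D2:**
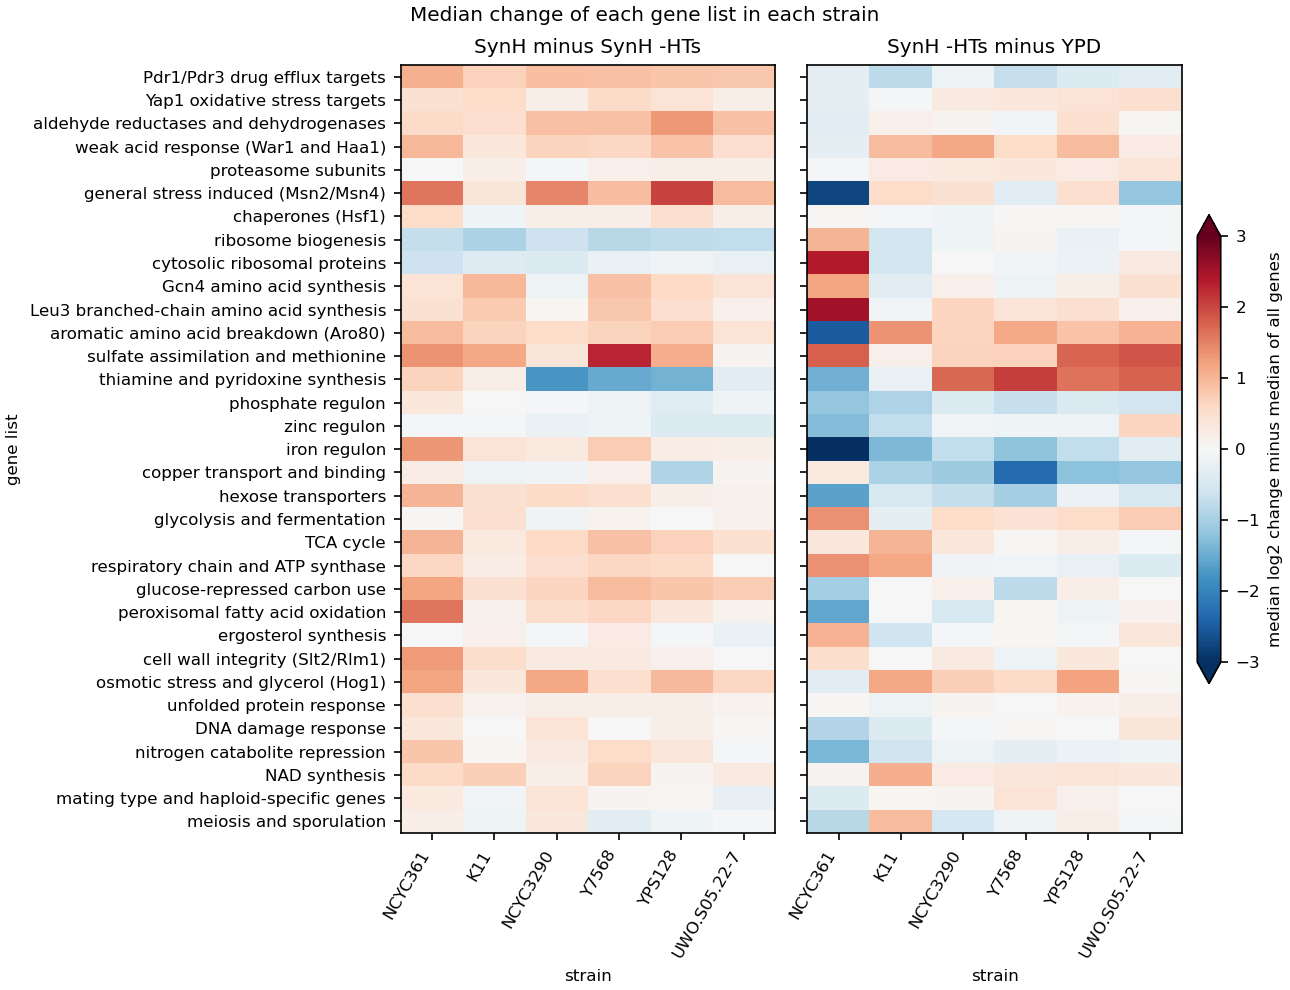
Median log2 change of each of the 33 gene lists in each strain, relative to the median of all genes, for the toxin response (left) and the base medium response (right), with colours limited to 3 in either direction. General stress genes were above all genes in the toxin response of the 6 strains (0.36 to 2.03) and ribosome biogenesis genes below (-0.95 to -0.62), while NCYC361 stood apart in the base medium response, with the iron regulon at -5.47.

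The base medium itself changed transcripts of the weak acid response, sugar transport and iron uptake relative to YPD. YRO2 (YBR054W, chromosome II 343101 to 344135), a plasma membrane protein gene of the weak acid response, was 626-fold higher in SynH -HTs (9.29 ± 0.18, adjusted p = 2.6e-21, range over strains 6.96 to 10.80). The pyruvate decarboxylase gene PDC5 was 63.5-fold higher (5.99 ± 0.24) and the low-affinity glucose transporter gene HXT1 14.6-fold higher (3.87 ± 0.11). The glucose transporter gene HXT2 (YMR011W, chromosome XIII 288079 to 289704) was 346-fold lower (-8.44 ± 0.26, adjusted p = 1.45e-17), and the phosphate transporter gene PHO84 was 108-fold lower (-6.75 ± 0.16, range -10.69 to -2.30). PHO84 overlaps an annotated noncoding gene and is uncertain for that reason.

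The other rises among the 12 largest were YGP1 (4.77 ± 0.22), MRH1 (3.67 ± 0.12), RTC3 (3.64 ± 0.25), the glycerol synthesis genes GPP2 (3.54 ± 0.16) and GPD1 (2.67 ± 0.11), FSH1 (2.75 ± 0.08), NRE1 (2.64 ± 0.07), STP4 (2.49 ± 0.12) and TPO2 (2.59 ± 0.08), which has a near-identical copy. The other falls were the copper transporter gene CTR3 (-5.96 ± 0.30, with at most 2 reads in each medium in NCYC361), the iron uptake genes FIT2 (-5.38 ± 0.35), SIT1 (-5.16 ± 0.22), FRE4 (-4.74 ± 0.25), FRE1 (-3.82 ± 0.14) and FIT3 (-3.52 ± 0.19), TIS11 (-3.36 ± 0.28), the aldehyde dehydrogenase gene ALD4 (-4.02 ± 0.21), ATO3 (-3.40 ± 0.15) and YGR035C (-5.28 ± 0.16). YGR035C had at most 3 reads per strain in SynH -HTs, so its fold depends on the added read. The changes ranged widely over strains for FIT3 (-9.81 to -0.11), FIT2 (-10.32 to -1.14), CTR3 (-9.18 to -0.89), TIS11 (-7.63 to -1.05), ALD4 (-6.97 to -2.22), RTC3 (0.82 to 6.85), PDC5 (2.64 to 7.84), GPD1 (0.41 to 5.32), GPP2 (0.3 to 5.17), HXT1 (1.53 to 6.32) and TPO2 (0.47 to 4.99). The -0.89 of CTR3 belongs to NCYC361, with 1 read in YPD and 0 in SynH -HTs, so no fall was measured in that strain. CTR3 met the rule of the same sign in all 6 strains only through that value. PDR5 (-2.20 ± 0.09), SNQ2 (-1.66 ± 0.08) and MCH4 (-0.99 ± 0.14) fell. These genes rose in the toxin response, which uses the same SynH -HTs libraries with opposite sign. The rise and the fall are therefore not independent, and neither gives the change from YPD to SynH. RPN4 (-0.34 ± 0.12, adjusted p = 0.0243) and YAP1 (-0.41 ± 0.16, adjusted p = 0.0338) passed narrowly and no longer did so after quantile normalization, with a replicate block or without NCYC361. RPN4 lost its call in 14 and YAP1 in 21 of 58 alternatives. Over the alternatives adjusted p ranged from 0.000134 to 0.563 for RPN4 and from 6.95e-06 to 0.968 for YAP1. RPN4 also lost its call without replicate 2 of UWO.S05.22-7 in YPD (adjusted p = 0.053) and without replicate 2 of SynH -HTs of any strain but K11 (adjusted p = 0.0542 to 0.0627). YAP1 lost it without replicate 2 of SynH -HTs of any strain (adjusted p = 0.0718 to 0.0868), and in YPD without replicate 1 of K11, YPS128 or UWO.S05.22-7 or replicate 2 of NCYC361, NCYC3290 or Y7568 (adjusted p = 0.0514 to 0.0617). LEU3 did not pass (-0.24 ± 0.19, adjusted p = 0.292), and its change was 0.17 after quantile normalization.

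The iron regulon, phosphate regulon, hexose transporter and drug efflux lists fell in the base medium. All 22 iron regulon genes fell (22 adjusted over the list alone), with a median 1.55 below that of all genes, and SIT1, FRE4, FIT3 and FTH1 (-1.34 ± 0.08) as examples. Much of that size came from NCYC361, where the list median was -5.47 relative to all genes, against -1.35 to -0.32 in the other strains, and without NCYC361 19 genes fell with a median 0.77 below that of all genes. Of 14 phosphate regulon genes 12 fell (13 adjusted over the list alone), with PHO84, VTC3 (-1.54 ± 0.13) and VTC4 (-0.86 ± 0.09) as examples. Of 10 hexose transporter genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), HXT1 being the rise and HXT3 (-0.77 ± 0.08) a smaller fall. Of 14 drug efflux targets 12 fell and 1 rose (13 and 1 adjusted over the list alone), with TPO4 (-1.78 ± 0.11) and YOR1 (-1.10 ± 0.07) beside PDR5 and SNQ2. These 4 lists passed camera with both correlations (adjusted p = 0.0211 to 0.0275 with an estimated correlation). Of 17 genes under nitrogen catabolite repression 13 fell (15 adjusted over the list alone), with MEP1 (-2.26 ± 0.13), DUR12 (-1.82 ± 0.16), GAP1 (-1.39 ± 0.15) and PUT1 (-1.72 ± 0.20) as examples (adjusted p = 0.0672 with an estimated correlation). These 13 falls became 7 after quantile normalization and 8 after median scaling, and the 12 of drug efflux targets became 8 after each. Of 24 general stress genes 17 fell and 1 rose (17 and 3 adjusted over the list alone), with GDB1 (-1.66 ± 0.14), GSY2 (-1.54 ± 0.17), PGM2 (-1.42 ± 0.17) and GPH1 (-2.19 ± 0.27) as examples (adjusted p = 0.498 with an estimated correlation). Without NCYC361, 5 general stress genes fell and 2 rose, and 11 phosphate regulon, 6 hexose transporter, 10 drug efflux and 8 nitrogen catabolite repression genes fell. Copper genes fell in 3 of 6, FRE1, CTR3 and CTR1 (-3.07 ± 0.18), and rose in 1, CRS5 (0.56 ± 0.14), with the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.125).

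Other lists rose. Of 23 genes of sulfate assimilation and methionine synthesis 17 rose and 0 fell (18 and 0 adjusted over the list alone), with a median 1.05 above that of all genes, and MET10 (1.66 ± 0.08), MET3 (2.13 ± 0.12), MET6 (1.56 ± 0.11) and MET17 (1.64 ± 0.11) as examples. Of 16 glycolysis and fermentation genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with ENO1 (2.17 ± 0.12), TPI1 (0.41 ± 0.05), FBA1 (0.40 ± 0.06) and TDH2 (1.19 ± 0.10), which has a near-identical copy. Of 14 weak acid response genes 6 rose and 5 fell (6 and 5 adjusted over the list alone), with YRO2, TPO2, YGP1 and YPC1 (1.71 ± 0.12) among the rises. Of 7 genes of aromatic amino acid breakdown 3 rose and 2 fell (3 and 2 adjusted over the list alone), the rises being PDC5, ARO9 (1.04 ± 0.10, range over strains -3.39 to 3.2) and ARO10 (1.44 ± 0.15, range -6.05 to 4.07), while BAT2 was 9.61-fold lower (-3.26 ± 0.14). The median of that list relative to all genes was -2.50 in NCYC361 and 0.65 to 1.35 in the other strains. These 4 lists passed upward with both correlations (adjusted p = 0.00172 to 0.0343 with an estimated correlation). Of 14 thiamine and pyridoxine genes 9 rose and 3 fell (9 and 3 adjusted over the list alone), with THI7 (1.03 ± 0.09), PHO3 (1.30 ± 0.17), THI73 (2.03 ± 0.26) and THI20 (1.76 ± 0.27) as examples (adjusted p = 0.133 with an estimated correlation). The median of the thiamine and pyridoxine list relative to all genes was -1.43 in NCYC361 and -0.2 in K11, and 1.64 to 2.08 in the other strains. Osmotic stress genes rose in 7 of 15 and fell in 5 (8 and 5 adjusted over the list alone, adjusted p = 0.082 with an estimated correlation). Branched-chain amino acid genes rose in 6 of 10 and fell in 2 (6 and 2 adjusted over the list alone, adjusted p = 0.0622 with an estimated correlation). After median scaling the falls were 2 weak acid, 1 thiamine and pyridoxine and 3 osmotic stress genes, and after quantile normalization 2, 1 and 4.

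Further lists depended on the scaling. The median of all genes lay at -0.31, and whether this caused the dependence was not tested. Ribosomal protein genes rose in 15 of 132 and fell in 15 (10 and 9 adjusted over the list alone), with a median of -0.02 and an upward test (adjusted p = 0.563 with an estimated correlation), and after median scaling 70 rose and 2 fell, while without NCYC361 0 rose and 77 fell. Gcn4 targets rose in 11 of 40 and fell in 14 (11 and 15 adjusted over the list alone, adjusted p = 0.503 with an estimated correlation), respiratory genes rose in 5 of 31 and fell in 8 (5 and 8 adjusted over the list alone, adjusted p = 0.498 with an estimated correlation), and tricarboxylic acid cycle genes rose in 6 of 18 and fell in 6 (6 and 6 adjusted over the list alone, adjusted p = 0.498 with an estimated correlation). After quantile normalization these became 20 and 4, 13 and 2, and 10 and 3. Glucose-repressed genes fell in 7 of 11 (8 adjusted over the list alone, adjusted p = 0.133 with an estimated correlation), which became 4 after quantile normalization and after median scaling. The lists that follow did not pass camera, and their bracketed counts are those adjusted over the list alone. Yap1 targets rose in 3 of 17 and fell in 5 (3 and 5), aldehyde genes in 4 and 11 of 20 (4 and 11), and proteasome genes in 0 and 2 of 33 (0 and 0), which became 7 and 3, 6 and 5, and 8 and 1 after quantile normalization. Ergosterol genes rose in 5 of 24 and fell in 13 (5 and 13), cell wall genes in 5 and 7 of 19 (6 and 7), and NAD synthesis genes in 2 and 3 of 10 (2 and 3), and the first became 8 and 5 after median scaling and the others 7 and 5, and 5 and 2, after quantile normalization. Ribosome biogenesis genes rose in 1 of 45 and fell in 13 (1 and 9), and unfolded protein response genes in 1 and 8 of 14 (1 and 8), which became 4 and 3 in both lists after median scaling. Chaperone genes rose in 1 of 20 and fell in 10 (1 and 10), zinc regulon genes in 2 and 6 of 9 (2 and 6), peroxisomal genes in 0 and 6 of 11 (1 and 8), and DNA damage genes in 0 and 8 of 13 (0 and 9). After median scaling these became 5 and 8, 2 and 4, 2 and 5, and 0 and 3, and after quantile normalization 1 and 7, 2 and 4, 2 and 5, and 0 and 3. Haploid-specific genes rose in 1 of 13 and fell in 2 (1 and 1), and sporulation genes in 1 and 3 of 10 (1 and 4), which became 2 and 1, and 1 and 0, after median scaling. Medians and means were negative while camera pointed upward, relative to all genes, for the Yap1, aldehyde, proteasome, ribosome biogenesis, ribosomal protein, Gcn4, ergosterol, cell wall, haploid-specific and sporulation lists. The respiratory list had a median of -0.01 and a mean of 0.00, the NAD list a median of 0.02 and a mean of -0.06, and both pointed upward.

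In the base medium response 2678 genes passed, 402 higher and 2276 lower, and after quantile normalization 1197 were higher and 1080 lower. Only 1454 genes were called both ways in the same direction, and no gene was called in opposite directions. Of those that passed, 81 higher and 441 lower genes exceeded 2-fold. Without NCYC361, 1638 genes passed. Strains as the unit gave 1544 genes, means over strains for each medium and replicate number gave 217, and leaving out the 6 SynH -HTs libraries of replicate 1 gave 4494. Of the genes named for the base medium response 16 lost the call with strains as the unit, ARO9, ARO10, GDB1, GSY2, PGM2, GPH1, MET6, THI7, PHO3, THI73, THI20, CRS5, TPI1, FBA1, RPN4 and YAP1 (adjusted p = 0.0534 to 0.275). With means over strains 9 lost it, PGM2, THI20, VTC4, CRS5, TPI1, FBA1, RPN4, YAP1 and MCH4 (adjusted p = 0.0641 to 0.507). With replicate 1 of SynH -HTs alone, all 22 iron regulon genes, 12 drug efflux and 11 phosphate regulon genes fell and 16 sulfate genes rose, and with replicate 2 alone the counts were 22, 12, 14 and 18. Cell wall genes had 5 rises and 9 falls with replicate 1 alone and 7 and 7 with replicate 2 alone, and proteasome genes 13 and 0 against 0 and 31. The toxin and base medium responses share the SynH -HTs libraries with opposite sign. Past both thresholds, 550 genes rose with toxins and fell in the base medium, against 434.3 for independent lists. For the reverse it was 76 against 42.5, for rises in both 160 against 76.7, and for falls in both 198 against 240.4. The correlation of the responses across genes was -0.1, and -0.5 in simulations with no effect.

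Against YPD, the complete hydrolysate combined both responses. YRO2 was 992-fold higher in SynH than in YPD (9.95 ± 0.18, adjusted p = 2.76e-22, range over strains 7.24 to 11.67). PDC5 (7.14 ± 0.24), YGP1 (6.28 ± 0.22) and TDH1 (5.64 ± 0.18) were 141-fold, 77.8-fold and 49.8-fold higher, and ADH7 had a mean log2 change of 8.15 ± 0.13, with K11 at 1 read or fewer in each medium, so no rise was measured in that strain. HXT2 was 325-fold lower (-8.35 ± 0.26), FRE4 46.2-fold (-5.53 ± 0.25), PHO84 33.6-fold (-5.07 ± 0.16), SIT1 24.9-fold (-4.64 ± 0.22) and FRE1 17.5-fold lower (-4.13 ± 0.14). The rule for naming required the same sign in all 6 strains, and ADH7 met it only with K11 at 1 read or fewer in each medium. In total 2885 genes passed, 856 higher and 2029 lower, with the median of all genes at -0.23, and after quantile normalization 1457 were higher and 1696 lower. Of these, 271 higher and 471 lower genes exceeded 2-fold, and means over strains for each medium and replicate number gave 474 genes. This comparison is the sum of the toxin and base medium responses and shares their libraries.

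Within single strains the toxin response was led by a few shared genes. ADH7 was the largest rise in NCYC361 (12.90 ± 0.33), NCYC3290 (11 ± 0.33), Y7568 (12.69 ± 0.33) and YPS128 (12.40 ± 0.33). In YPS128 it had 2 reads in SynH -HTs, so the size depends on the added read, and 131896 in SynH. These reads are not scaled for depth, and SynH replicate 2 of YPS128 held 32836466 reads in genes. ADH7 had 7 reads in SynH -HTs in NCYC361 and 6 in Y7568, so the sizes in these strains also depend in part on the added read. In K11 the largest rises were SNG1 (3.98 ± 0.49), TDH1 (3.95 ± 0.45) and ARG1 (3.11 ± 0.27), and in UWO.S05.22-7 they were PDR12 (5.39 ± 0.21), SNG1 (5.23 ± 0.49) and INO1 (4.5 ± 0.34). NCYC361 also had ARO10 (6.94 ± 0.38) and HSP26 (6.34 ± 0.62), NCYC3290 had TDH1 (6.71 ± 0.45) and YPR127W (5.27 ± 0.23), Y7568 had SUL2 (5.08 ± 0.29) and ARI1 (4.97 ± 0.33), and YPS128 had HXK1 (6.29 ± 0.58) and TDH1 (5.98 ± 0.45). Thiamine pathway genes led the falls in NCYC3290 (THI73, -4.95 ± 0.63), Y7568 (THI73 at -4.60 ± 0.63, THI2 at -4.04 ± 0.69, PHO3 at -3.38 ± 0.40) and YPS128 (THI2 at -5.14 ± 0.69, THI73 at -4.29 ± 0.63, THI20 at -3.85 ± 0.66). NCYC3290 also had falls of DIP5 (-3.91 ± 0.38) and PET18 (-3.80 ± 0.59). The largest falls were TCB2 (-2.24 ± 0.28), THI7 (-2.13 ± 0.22) and YJL213W (-1.78 ± 0.35) in NCYC361, YHB1 (-1.71 ± 0.47), YNL095C (-1.63 ± 0.32) and RIX1 (-1.47 ± 0.29) in K11, and FUI1 (-3.57 ± 0.31), PNS1 (-2.21 ± 0.46) and ZRT1 (-2.21 ± 0.35) in UWO.S05.22-7. YHB1 in K11 (adjusted p = 0.0429) lost its call in 21 of 49 alternatives, among them the removal of any single K11 library of SynH or SynH -HTs, the highest being without replicate 2 of SynH, and its adjusted p ranged from 0.00485 to 0.328. In K11, RIX1 lost its call without replicate 1 of SynH -HTs (adjusted p = 0.0758, range 4e-05 to 0.0758) and YNL095C without replicate 1 of SynH (adjusted p = 0.095, range 0.00112 to 0.095). YJL213W in NCYC361 lost it with 5 added reads (adjusted p = 0.216), with voom (0.0568) and without replicate 2 of SynH (0.0574), over a range from 5.11e-05 to 0.216. PNS1 in UWO.S05.22-7 lost it with voom (adjusted p = 0.0517) and without replicate 1 of SynH or replicate 2 of SynH -HTs (adjusted p = 0.0615 and 0.0734, range 0.00213 to 0.0734).

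The number of genes that passed within a strain was 619 in NCYC361 (526 higher and 93 lower, 449 and 289 after quantile normalization) and 231 in K11 (143 and 88, 310 and 316). It was 320 in NCYC3290 (269 and 51, 231 and 128), 368 in Y7568 (281 and 87, 280 and 160), 406 in YPS128 (324 and 82, 303 and 175) and 170 in UWO.S05.22-7 (147 and 23, 103 and 35). With the replicate number as a block, UWO.S05.22-7 had 113. These counts rest on 2 libraries against 2, and the difference between strains in the count was not tested. Without replicate 2 of SynH the counts were 324 in NCYC361, 80 in K11, 133 in NCYC3290, 195 in Y7568, 205 in YPS128 and 64 in UWO.S05.22-7, and without replicate 1 of SynH they were 118 in K11, 207 in NCYC3290 and 238 in Y7568. Without replicate 1 of SynH -HTs they were 148 in K11, 181 in NCYC3290, 235 in Y7568 and 294 in UWO.S05.22-7, and without replicate 2 of SynH -HTs they were 356 in NCYC361, 116 in K11, 185 in NCYC3290 and 229 in YPS128.

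Strain differences in the toxin response are described by the 10 genes with the smallest adjusted p, and gene lists were not tested for such differences. ADH7 gave the smallest adjusted p (3.12e-16). It had 59942 reads in the 2 SynH libraries of NCYC361, 378 in UWO.S05.22-7 and 0 in K11. The adjacent genes RDS1 and AAD3 together had 1 read in the 6 K11 libraries, against 754 and 153 reads in UWO.S05.22-7, the next lowest strain. YPR127W rose by 4.93 in NCYC361 and 5.27 in NCYC3290 and had changes of 0.10 to 1.47 in the other strains (adjusted p = 7.14e-11). PDR12 changed least in K11 (2.07) and most in NCYC361 (6.29). Its log2 RPKM in SynH was nevertheless higher in K11 (10.83 and 10.9) than in NCYC361 (9.53 and 9.78). In SynH -HTs it was 8.48 and 9.1 against 3.27 and 3.46. The change of ARI1 ranged from 0.33 in K11 to 6.25 in NCYC361, that of ARO10 from 0.33 in UWO.S05.22-7 to 6.94 in NCYC361, and that of ARO9 from -0.15 to 3.94 in the same strains. The SD of the level between strains was smaller in SynH than in SynH -HTs for PDR12 (0.44 and 1.93), ARO10 (1.55 and 2.85) and ARO9 (1.76 and 2.63). For ARI1 it was larger (1.9 and 0.67).

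**Figure D3:**
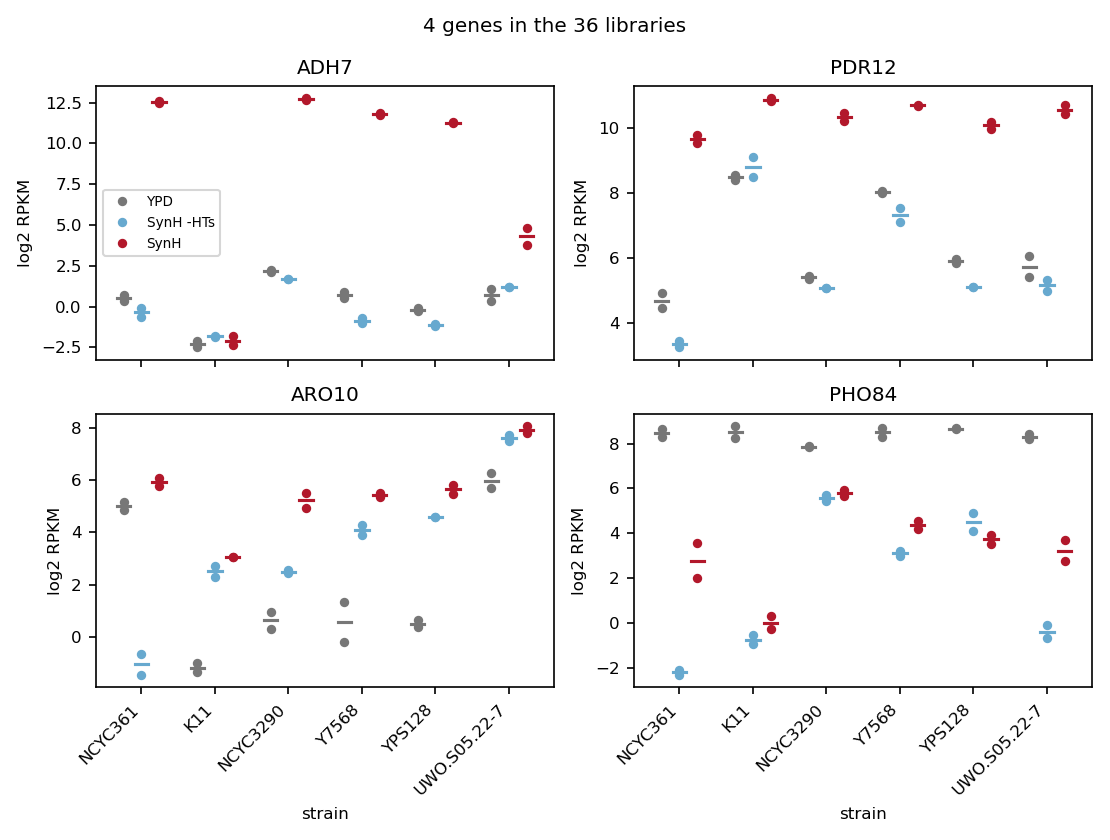
Log2 RPKM of ADH7, PDR12, ARO10 and PHO84 in each of the 36 libraries (points) with the mean of each strain and medium (bars). ADH7 lay at the level of the added read in K11 and at 11.26 to 12.70 in the SynH means of NCYC361, NCYC3290, Y7568 and YPS128.

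The remaining genes named were SUC2 (0.12 to 3.43), PHO84 (-0.77 to 4.99), MET10 (-0.07 to 3.00) and YJL213W (-1.78 to 3.18). In total 141 genes passed limma's F test, against 78 with the replicate number as a block, 83 without NCYC361, 71 without K11 and 93 without NCYC3290. After quantile normalization 145 passed, 93 of them among the 141. With a block for each medium and number, added after the data were seen, 421 passed. NCYC361 was the strain farthest from the others in 50 of the 141 genes and K11 in 36.

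The base medium response differed among strains in far more genes, 1752, and NCYC361 was the farthest strain in 1382 of them. In NCYC361 the cytochrome c gene CYC1 rose by 7.20 from YPD to SynH -HTs, against -1.25 to 2.17 in the other strains (adjusted p = 1.91e-11). The iron reductase gene FRE2 changed by -9.29 in NCYC361 and by -0.67 to 1.62 in the others. ARO10 (-6.05 against 1.61 to 4.07), ARO9 (-3.39 against 0.42 to 3.2) and HBN1 (-4.22 against 1.49 to 3.67) went in opposite directions in NCYC361 and the other strains. The sterol demethylase gene ERG11 (2.84 against -1.19 to -0.18), FTH1 (-4.64 against -0.98 to -0.22), GLT1 (3.44 against -0.42 to 0.34) and TPO2 (0.47 against 1.30 to 4.99) also placed NCYC361 at an end. PHO84 ranged from -10.69 in NCYC361, where it had 2 reads in SynH -HTs, to -2.30 in NCYC3290. Without NCYC361, 323 genes passed, and leaving out the 6 SynH -HTs libraries of replicate 1 gave 2814. After quantile normalization 1907 passed, 1196 of them among the 1752. A block for each medium and number, added after the data were seen, gave 4018.

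Mean levels over the 3 media differed among strains in 4076 genes. The sulfur transfer gene RDL1 had a mean log2 RPKM of 3.2 in YPS128 and 3.64 in UWO.S05.22-7, against 7.16 to 8.4 in the other strains (adjusted p = 2.01e-21). YLR046C (10.36) and the nicotinamide riboside transporter gene NRT1 (8.97) were highest in K11, against at most 5.49 and 3.84 elsewhere. AIF1 had 0 reads in NCYC361 and COS12 had 0 reads in K11, while their means elsewhere were 3.79 to 5.83 and 2.65 to 4.53. AAD6 lay at -1.64 in Y7568 and -1.54 in NCYC361, each with at most 1 read per medium, and at 7.43 in K11. COS6 lay at -2.32 in Y7568 and 6.21 in K11, and ARO9 at 9.72 in UWO.S05.22-7 against 3.14 to 5.29. The mitochondrial genes AI1 and AI2, which lie in introns of another gene and overlap it, had levels above 8 in some strains and below -2 in others. The reference used for alignment is not given in the sources used here. Sequence differences between the strains and that reference may therefore enter these levels.

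Between resistant and sensitive strains 2 genes passed limma's test, both in SynH -HTs. The acid phosphatase gene PHO3 was higher in the 3 resistant strains (log2 RPKM 8.38 ± 0.96 SD, n = 3) than in the 2 sensitive strains (1.07 ± 0.44 SD, n = 2), a difference of 7.31 ± 0.52 (adjusted p = 0.00223). The glycerol phosphatase gene GPP2 was lower in the resistant strains (7.35 ± 0.11 SD, n = 3) than in the sensitive strains (9.40 ± 0.37 SD, n = 2), by -2.05 ± 0.23 (adjusted p = 0.0467). For both genes every resistant strain lay on one side of every sensitive strain. NCYC3290 lay at 10.23 for PHO3 and at 8.41, between the classes, for GPP2. GPP2 lost its call in 8 of 13 alternatives and PHO3 in 2. Both lost it without the variance trend (adjusted p = 0.101 for PHO3 and 0.267 for GPP2) and with NCYC3290 counted as sensitive (adjusted p = 0.488 for both). GPP2 also lost it after quantile normalization (adjusted p = 0.13), median scaling (0.141) and the base composition correction (0.111), with 0.1 added reads (0.0573), with NCYC3290 counted as resistant (0.208) and without replicate 1 of every strain (0.0888). Over the alternatives adjusted p ranged from 3.05e-15 to 0.488 for PHO3 and from 2.48e-06 to 0.488 for GPP2, the lowest with single libraries as the unit.

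No gene passed limma's test between the classes in the toxin response, in SynH or in YPD, where 469, 822 and 1042 of 5927 genes had an unadjusted p under 0.05. In the toxin response the 5 smallest p, none of which passed, belonged to THI6 (-1.75 ± 0.24, adjusted p = 0.208), YOL153C (2.25 ± 0.31), CSS1 (-1.41 ± 0.20), YFL041W-A (1.72 ± 0.29) and PHO3 (-3.63 ± 0.65, adjusted p = 0.324). In SynH they belonged to SPI1 (-3.43 ± 0.27, adjusted p = 0.0714), PHO3 (3.68 ± 0.33), YMR103C (-2.33 ± 0.24), SMP1 (-3.81 ± 0.43) and the sodium pump gene ENA1. ENA1 has near-identical copies, and it lay at 2.97 and 6.18 in the sensitive strains while Y7568, UWO.S05.22-7 and NCYC3290 had 0 reads in SynH. In YPD they belonged to GTT1 (-4.38 ± 0.32, adjusted p = 0.0569), THI6 (-3.62 ± 0.30), TIR1 (-6.85 ± 0.63), GDH2 (-2.58 ± 0.28) and PAU15 (-4.46 ± 0.53, with a near-identical copy). The medians of all genes lay at -0.36 in SynH, -0.46 in SynH -HTs and -0.42 in YPD for resistant minus sensitive. Leaving out replicate 2 of every strain gave 3 genes in the toxin response and 3 in YPD, and single libraries as the unit gave 36, 1706, 1856 and 2719 genes for the toxin response, SynH, SynH -HTs and YPD, but libraries of a strain are not replicates of a class.

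Gene lists separated the classes in the toxin response only with the preset correlation. Ribosomal protein genes had a median difference of 0.42 between resistant and sensitive strains (0 of 132 past the threshold, 96 adjusted over the list alone, adjusted p = 3.51e-26 against 0.863 with an estimated correlation). Thiamine and pyridoxine genes had a median of -1.52 (0 of 14, 5 adjusted over the list alone, adjusted p = 2.38e-11 against 0.863 with an estimated correlation). Cell wall integrity (-0.52), iron regulon (-0.35, 1 adjusted over the list alone), sulfate assimilation (-0.31) and NAD synthesis genes (-0.32) passed downward with the preset correlation, and each had adjusted p = 0.863 with an estimated correlation. The 27 other lists did not pass, and none of their members passed over all genes. Adjusted over the list alone, 1 aldehyde gene was higher, 1 unfolded protein response gene lower, and 1 gene of aromatic amino acid breakdown higher and 1 lower. Camera pointed downward while median and mean were positive for the Yap1, Gcn4, branched-chain, ergosterol, DNA damage and respiratory lists, relative to a median of all genes of 0.10. Camera also pointed downward for genes under nitrogen catabolite repression (median 0.11, mean -0.10) and haploid-specific genes (median 0.02, mean -0.16).

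**Figure D4:**
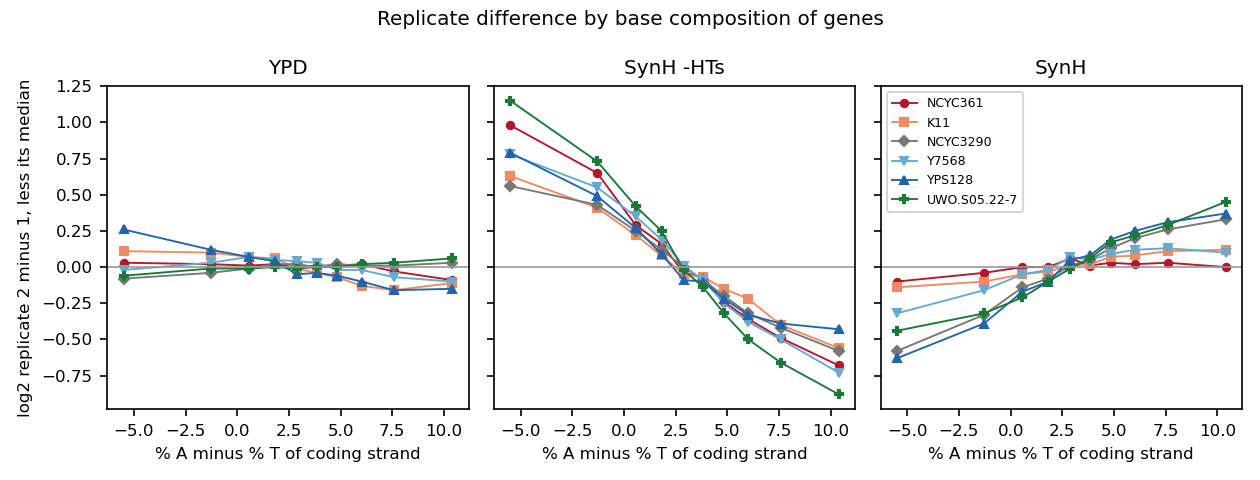
Median log2 difference of replicate 2 from replicate 1 in each of the 6 strains (coloured lines) and each medium, less the median of that strain over the genes shown. The genes are in 10 equal groups ordered by the share of A minus the share of T in the coding strand. The correlation across genes of the difference averaged over strains with that share was -0.73 in SynH -HTs, 0.64 in SynH and -0.20 in YPD.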

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

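The counts of other splits of the samples and the test on genes without a hydrophobic window were set before their results were seen, and the other tests in this part were chosen after. The splits within a medium and number were added after the other counts had been seen, and before their own. Strain differences were singled out because limma's test of the difference itself passed, in 141 genes for the toxin response and 1752 for the base medium response.

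In the toxin response the log2 change of ADH7 ranged from 3.13 to 12.90 in the 5 strains with reads. The upper end rests on 7 reads in SynH -HTs in NCYC361. K11, with 0 reads in both media, gave no measured change, so the gap of 13.16 computed with K11 at the added read is not a measured difference. The gap between the highest and the lowest strain was 5.16 on the log2 scale for YPR127W, 4.21 for PDR12 and 5.92 for ARI1. It was 6.62 for ARO10, 4.1 for ARO9, 3.31 for SUC2, 5.76 for PHO84, 3.07 for MET10 and 4.96 for YJL213W, which had 2 reads in SynH in NCYC361, the lowest strain. In the base medium response the gap was 8.45 for CYC1, 10.91 for FRE2, 10.11 for ARO10, 6.59 for ARO9 and 4.03 for ERG11. It was 4.42 for FTH1, 7.89 for HBN1, 4.51 for TPO2, 8.39 for PHO84, which had 2 reads in SynH -HTs in NCYC361, the lowest strain, and 3.86 for GLT1.

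The SynH -HTs libraries of replicate 2 differed from those of replicate 1 in the same genes in all 6 strains. Sampling noise of low depth is argued against by the correlations of the differences between pairs of strains, the lowest of which was 0.62 across genes. The mean difference had a correlation of -0.73 across 3980 genes with the share of A minus the share of T in the coding strand, and base composition may therefore be part of the cause. A response confined to membrane proteins, which are rich in T, is argued against by a correlation of -0.66 in the 2694 genes without a hydrophobic window. A difference in growth or harvest between the days was not tested and stays open.

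ADH7 had 0 reads in K11 in SynH, where 4 strains had 46207 or more. Low depth is argued against, since the K11 libraries would have held 184 reads at the level of the lowest other strain. ADH7 and the adjacent RDS1 and AAD3, on chromosome III from 309070 to 314981, had 2 reads in the 6 K11 libraries, and a variant or missing sequence in K11 relative to the reference is a candidate explanation. No genome sequence of K11 was analysed here, so the sequence itself was not examined.

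NCYC361 stood apart from the other strains in YPD, and it was the farthest strain in 1382 of the 1752 genes above. A mislabelled sample is argued against, since 75% of 12 genes, 9 of them, that set NCYC361 apart in the other media lay on the same side in both of its YPD libraries. The distance required of these genes was lowered to 1 on the log2 scale after stricter limits had left too few genes. A different overall scale is argued against by 1737 genes after median scaling. Ribosomal protein genes lay at -2.09 relative to the other strains in YPD, as a slower growth state at harvest would give. From YPD to SynH -HTs their median, relative to all genes, changed by 2.38 in NCYC361 and by -0.55 to 0.28 in the other strains. That argues against a level of these genes that is low in every medium. These data cannot separate a slower growth state from a lasting property of the strain that shows in YPD.

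Of 100 splits of the samples, the real one included, 3 gave as many genes as the toxin response (1757 against 2631 in the highest other split). That excludes at 0.05 a chance split of libraries taken as independent, but the libraries of a number deviate together across strains in SynH -HTs (correlations of 0.62 to 0.86) and less so in SynH (0.11 to 0.65). Exchanging SynH and SynH -HTs in replicate 2 alone gave 3504 genes, more than the real split, which points to a structure of the samples by replicate. That a part of the toxin count comes from this structure is therefore not excluded. Means over strains for each medium and number gave 190 genes, and these means allow too few splits for a share under 0.05. For the base medium response 1 of 100 splits gave as many (2678 against 2244), for the complete hydrolysate 1 of 100 (2885 against 292), and the exchange gave 0 genes in both. For strain differences in the base medium response 1 of 100 did so (1752 against 1389), and for the mean level 1 of 100 (4076 against 1290), so a chance split of libraries taken as independent was excluded at 0.05 for these 4 results. The base medium response uses the same SynH -HTs libraries as the toxin response, and the complete hydrolysate response the same SynH libraries, so a part of each count that comes from their shared deviations is not excluded. Means over strains for each medium and number gave 217 genes for the base medium response and 474 for the complete hydrolysate, and here too allow too few splits. For strain differences in the toxin response 5 of 100 splits gave as many (141 against 844), so chance could not be excluded in that fit, which leaves the shared deviations of a number in place, and the highest count points to a structure of the samples. A block for each medium and number was then fitted, with strains exchanged only within a medium and number. In that fit 2 of 100 splits gave as many (421 against 935). The same blocked splits gave 1 of 100 for the base medium response (4018 against 1486) and 1 of 100 for the mean level (5490 against 1960). In the splits for strain differences, blocked or not, libraries of different strains fall into the same group. Differences in level between strains then add to the spread within groups. A low share of such splits therefore cannot show that the responses themselves differ among strains.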

How the results depend on the processing

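Median scaling, the base composition correction, voom, the block for each medium and number, the crossed block, means over strains, and the exclusion of either SynH -HTs replicate were chosen after the data were seen. The cause was not tested for any change below unless fewer samples were used. With quantile normalization K11 had 626 genes, and the classes differed in 1 gene in SynH and 1 in SynH -HTs. With median scaling K11 had 393, and the classes differed in 1 gene in SynH, 1 in SynH -HTs and 2 in YPD. For the classes in SynH -HTs, no filter gave 4 genes, no variance trend 0, 0.1 added reads 1 and the base composition correction 1. Adding 5 reads gave 1 gene between the classes in SynH and 3 in YPD. NCYC3290 counted as resistant gave 1 gene in SynH -HTs and 65 in YPD, and counted as sensitive 0 in SynH -HTs. Single libraries as the unit gave 36, 1706, 1856 and 2719 genes for the toxin response, SynH, SynH -HTs and YPD, and 24, 1753, 1892 and 2754 with a replicate block.

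With the replicate number as a block UWO.S05.22-7 had 113 genes and strain differences in the toxin response 78, and no other count of genes moved beyond 1.5 times. Within a strain, the 6 correlations of the deviations of a number were -0.64 to -0.11 between SynH and SynH -HTs, -0.15 to 0.44 between SynH -HTs and YPD and -0.43 to 0.21 between SynH and YPD. A pairing of media by the same number would need positive correlations, and the negative ones between SynH and SynH -HTs are why these numbers were also crossed. With the numbers of SynH crossed, the toxin response had 2008 genes, the base medium response 3139 and strain differences 133 and 2093. A block for each medium and number gave 421 and 4018 strain differences in the toxin and base medium responses.

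Strains as the unit gave 617 genes in the toxin and 1544 in the base medium response. Means over strains for each medium and number gave 190, 217 and 474 for the toxin, base medium and complete hydrolysate responses, from 2 values against 2. Without the strain NCYC361 the base medium response had 1638 genes and strain differences 83 in the toxin and 323 in the base medium response. Strain differences in the toxin response numbered 71 without K11 and 93 without NCYC3290. Without the 6 SynH -HTs libraries of replicate 2, the toxin response had 2996 genes, K11 557, Y7568 714 and UWO.S05.22-7 454. Without those of replicate 1, the toxin response had 3707, the base medium response 4494, NCYC361 1158, NCYC3290 497, YPS128 900, UWO.S05.22-7 1803, and strain differences in the base medium response 2814. Groups left with 1 library were assumed to vary like the others.

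With 1 library left out in turn, counts were 1574 to 1995 for the toxin, 2216 to 3461 for the base medium and 2678 to 3104 for the complete hydrolysate response. They were 324 to 696 in NCYC361, 80 to 314 in K11, 133 to 368 in NCYC3290, 195 to 425 in Y7568, 205 to 469 in YPS128 and 64 to 294 in UWO.S05.22-7. Strain differences were 106 to 158, 1242 to 2374 and 3757 to 4937 for the toxin response, the base medium response and the level. With a replicate left out of every strain, the classes differed in 0 to 3 genes in the toxin response, 0 to 0 in SynH, 2 to 2 in SynH -HTs and 0 to 3 in YPD.

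With an estimated correlation 10 gene lists passed in the toxin response, 8 in the base medium response and 0 between the classes. With fry of limma, which tests each list by itself, 29, 23 and 0 lists passed in the same order. LEU3 changed sign in the base medium response to 0.17 after quantile normalization, 0.03 after median scaling and 0.24 without SynH -HTs replicate 2, and in the toxin response to 0.38 without SynH -HTs replicate 1. YAP1 in the toxin response was -0.01 without SynH -HTs replicate 2. Of the named genes past the threshold, 32 lost the call with strains as the unit (16 in the toxin and 16 in the base medium response), 30 with means over strains (21 and 9), and at most 3 under each other setting. Of 8700 values of the 150 list members not named, 10 changed sign, 5 of them in genes past the threshold. Gene lists were not tested with libraries left out 1 at a time, voom was not run for the classes, and size factors were not run on the recovered reads. At the depth of 2204823 reads in genes in the shallowest library, changes of genes with few reads can be understated. With unequal library totals the added read can also give such genes a change that was not measured.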

Other observations

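All tests in this part were chosen after the values were seen. NCYC361 and K11 had distinct profiles in YPD. Relative to the median of the other strains, NCYC361 had medians of 3.74 for the iron regulon, 3.29 for general stress genes, 2.29 for haploid-specific genes and 1.94 for peroxisomal genes on the log2 scale, and of -1.6 for respiratory genes and -1.45 for branched-chain amino acid genes. K11 had medians of 4.16 for thiamine and pyridoxine genes, 2.62 for sporulation genes, 2.22 for sulfate and methionine genes and 2.16 for genes under nitrogen catabolite repression. These medians describe 2 libraries per strain and were not tested. The thiamine synthesis gene THI4 had a mean log2 RPKM of 11.66 in YPD, 12.83 in SynH -HTs and 11.69 in SynH in K11, against -0.22 to 4.22 in the other strains and media, and its level differed among strains (limma adjusted p = 1.27e-15).

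Some genes lacked reads in a single strain and had at least 10 in every library of the others. In NCYC361 these were AQY3 and AIF1, each with 0 reads. In K11 they were RDS1, with 1 read, and AAD3 and COS12, with 0. MAL13 had 0 reads in NCYC3290 and ARR1 had 0 in UWO.S05.22-7. No such gene was found in Y7568 or YPS128.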
